A study of Homo sapiens with 4 samples.

How the data were processed

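The series holds RNA sequencing of total RNA from HEK293A cells in 4 libraries, 2 that received the empty vector (shControl) and 2 that received a short hairpin RNA against CRY1 (shCRY1), with libraries prepared and sequenced by a commercial provider per the labels' protocols. Groups and replicate numbers were taken from the sample titles. For shCRY1 replicate 2 another label field names CRY2 as the target, and the title was followed. The submitters' processing notes name FastQC, featureCounts, edgeR and the hg38 build, without versions. The aligner, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be separated. The sequence of the hairpin is also not given there.

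The authors deposited one table per library with log2 values for 28395 genes, and no count table was used here. The values had the form of log2 CPM with a prior count of 2 scaled to library size: all 4 tables shared one lowest value, and above it the values stepped in whole multiples of a constant for each library. Inverting this form gave whole reads for 100% of values in every library, within a tolerance of 0.05 reads, the largest deviation being 0.00212 reads. Rebuilding the deposited log2 values from those reads left a difference of at most 5.46e-09. The recovered totals were 33656579 and 45816680 reads for shControl and 34278776 and 47536966 for shCRY1, with scaling factors of 0.972, 1.02, 0.988 and 1.02 built into the values. Replicate 2 was deeper than replicate 1 in both groups. Each depth class thus held 1 library per group, too few for a test within it. The 10 most abundant genes took 6.41% to 6.85% of reads. Every pair of libraries, replicates included, differed beyond sampling noise, with 51.6% to 61.4% of genes outside the Poisson expectation, so no library was counted as a duplicate.

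The fixed plan had named a quasi-likelihood test on counts. Because the tables hold log2 values, limma 3.58.1 (R 4.3.3) was used instead, on the deposited log2 CPM without a further pseudocount, with group as the only term, a mean-variance trend and robust empirical Bayes shrinkage. Genes with log2 CPM of at least -2 (0.25 CPM) in at least 2 libraries were tested, 16572 in all, of which 14381 are protein coding. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 CPM scale with its prior count of 2 and understate the change of genes with few reads. CPM printed in the text are recovered reads over the scaled library size. Gene symbols and coordinates were taken from the RefSeq table of GRCh38.p14 through Entrez identifiers, which matched for 27745 of 28395 genes, since some symbols in the tables had been turned into dates.

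Lists of genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, adjusted over 28 lists. Unless its mixed test is named, fry stands for its directional test. With an estimated correlation camera refers its statistic to the residual degrees of freedom, here 2, so hardly any list could pass in that form. The same camera test was run between the replicate numbers, with the groups ignored. CRY1 was left out of all of them. The mitochondrial genes were matched through RefSeq synonyms. The lists and the rule for named genes were set before the data were examined, as were the alternatives, except limma without robust shrinkage and the removal of genes with the 3′ UTR word. The rule took CRY1 and CRY2, the genes CCN1, CCN2, ANKRD1, AMOTL2, LATS2, YAP1 and WWTR1, and every measured core clock gene. It added the 12 genes that rose most and the 12 that fell most among called genes with a symbol, a mean of at least 2 CPM and no overlap between groups, and from each list up to 4 called members with the smallest p. The values of 1 gene under this rule are not reported here.

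Words of 7 bases were searched in the 3′ UTRs of GENCODE v29 (GRCh38), using for each gene the isoform with the longest coding sequence and a 3′ UTR of at least 50 bases, and as an alternative the longest annotated 3′ UTR. For 13997 genes and 15866 words present in at least 100 genes, the limma statistic was regressed on 3′ UTR length and GC content, and the mean residual of genes with a word was expressed as z. It was compared with 1000 permutations within length classes (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). In each permutation the leading word was chosen again, and the falling genes that held it and the median shift of uncalled genes were recorded. This search was added after the calls had been seen.

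The fit was tested on simulated reads with 200 genes changed in 10 runs for this comparison. It called 59.6% of genes changed 1.5-fold, 82.6% of those changed 2-fold and 99.0% of those changed 4-fold, with 4.55% false among calls and 0 calls of the wrong sign. The changes were planted in genes above a minimum of reads, and genes of similar level shared one dispersion. No difference between replicate numbers was simulated, so these shares need not hold for the data. The word search recovered 20 of 20 planted words over 13997 genes. These words were about as common as the leading word of the data and all carried one shift of -0.5 in the limma statistic. Rarer words and weaker shifts were not tried. Alternatives covered scaling, filters, the prior count, limma-voom on recovered reads, limma without robust shrinkage, thresholds, a block for the replicate number, each library left out in turn, and genes with the leading 3′ UTR word left out.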

Results

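Gene expression was measured by RNA sequencing in HEK293A cells, an adherent line derived from human embryonic kidney, to ask which transcripts differ when the circadian repressor CRY1 is knocked down. Cells carried either an empty vector delivered by lentivirus (shControl, 2 libraries) or a short hairpin RNA directed at CRY1 (shCRY1, 2 libraries). The shControl libraries held 33656579 and 45816680 reads assigned to genes, and the shCRY1 libraries held 34278776 and 47536966. Levels are given in CPM, reads scaled to library size, as mean ± SD over the 2 libraries of a group. Differences are log2 fold changes of shCRY1 over shControl, ± SE, with adjusted p from limma. The labels do not say that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

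CRY1 (Entrez 1407; chromosome 12, 106991364 to 107093549, GRCh38), a repressor of the CLOCK:BMAL1 transcription factor, fell by 1.47 ± 0.14 on the log2 scale in shCRY1 (limma, adjusted p = 0.000470). Its level was 39.8 ± 1.64 CPM in shControl and 14.3 ± 0.0366 CPM in shCRY1 (SD, n = 2 each), a 2.77-fold lower level. The shControl libraries held 41.0 and 38.6 CPM, and both shCRY1 libraries held 14.3 CPM. One label of shCRY1 replicate 2 names CRY2 as the target while its title names CRY1. In that library CRY1 was as low as in shCRY1 replicate 1, and CRY2 stood at 34.1 CPM against 22.6 and 17.3 CPM in the shControl libraries. CRY2 (chromosome 11, 45847118 to 45883244), the paralogous cryptochrome, measured 19.9 ± 3.71 CPM in shControl and 34.1 ± 0.0750 CPM in shCRY1 (SD, n = 2 each), a log2 difference of 0.79 ± 0.15 that narrowly missed the threshold (limma, adjusted p = 0.0535). CRY2 passed when shControl replicate 1 was left out (adjusted p = 0.00802).

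Of the clock genes, 2 period genes rose in shCRY1. PER2 (Entrez 8864; chromosome 2, 238244044 to 238300065), a repressor that works in a complex with the cryptochromes, rose 3.46-fold, from 4.50 ± 0.815 to 15.6 ± 1.44 CPM (SD, n = 2 each). This was a log2 change of 1.79 ± 0.22 (limma, adjusted p = 0.00297). PER3 (Entrez 8863; chromosome 1, 7784291 to 7845177) rose 1.86-fold, from 14.3 ± 1.84 to 26.5 ± 0.864 CPM (limma, adjusted p = 0.0333), a log2 change of 0.90. Without shCRY1 replicate 1 the rise stayed about as large, at 0.86, and missed the threshold (adjusted p = 0.0997). PER2 passed whichever library was left out.

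Among the 19 core clock genes measured besides CRY1, these 2 rose, 0 fell and 17 did not pass over all genes tested. With p-values adjusted over the list alone, 3 rose, CRY2 being the third. The activators CLOCK and BMAL1 differed by -0.18 ± 0.12 and 0.18 ± 0.16 on the log2 scale, and the levels of CLOCK were 46.4 ± 1.93 and 41.0 ± 0.842 CPM. Adjusted p was 0.810 for CLOCK, whose 3′ UTR holds 2 copies of the word described further on, and 0.866 for BMAL1. PER1 (0.24 ± 0.13), CIART (0.64 ± 0.33) and the nuclear receptor genes NR1D1 (0.14 ± 0.21) and NR1D2 (0.00 ± 0.11) did not pass either. Nor did BMAL2, NPAS2, RORA, NFIL3, BHLHE40, BHLHE41, CSNK1D, CSNK1E and TIMELESS, whose log2 differences lay between -0.23 for RORA and 0.21 for NFIL3. As a set the core clock genes missed the threshold (camera, adjusted p = 0.0769, and 0.929 with an estimated correlation). They passed in the mixed test of fry, which ignores direction (adjusted p = 0.00164). The set passed upward without shControl replicate 2 (adjusted p = 0.0197), without shCRY1 replicate 1 (0.0120), with the replicate number as a block (0.00660) and without genes holding the 3′ UTR word described further on (0.00634).

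Of 14 genes driven by CLOCK:BMAL1 through E-box elements, 11 were higher and 3 lower in shCRY1, with a median log2 difference of 0.23, and whether they passed as a set depended on the test. PER2 and PER3 rose, 0 fell and 12 did not pass, while 5 rose when adjusted over the list alone. The other 3, named after their values were seen, were TEF and HLF, which encode PAR bZIP transcription factors, and TSC22D3, a glucocorticoid-responsive gene. TEF measured 16.5 ± 1.82 and 28.9 ± 5.10 CPM, HLF 4.49 ± 0.821 and 9.16 ± 0.294 CPM, and TSC22D3 14.4 ± 1.30 and 22.5 ± 4.63 CPM in shControl and shCRY1. DBP, the third PAR bZIP gene, differed by 0.13 ± 0.20. The list passed with the preset correlation (camera, direction up, adjusted p = 3.34e-05), whereas it did not pass with an estimated one (adjusted p = 0.929 with an estimated correlation) or in the directional rotation test fry (adjusted p = 0.542). In the mixed test of fry, which ignores direction, it passed (adjusted p = 0.0182).

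**Figure D1:**
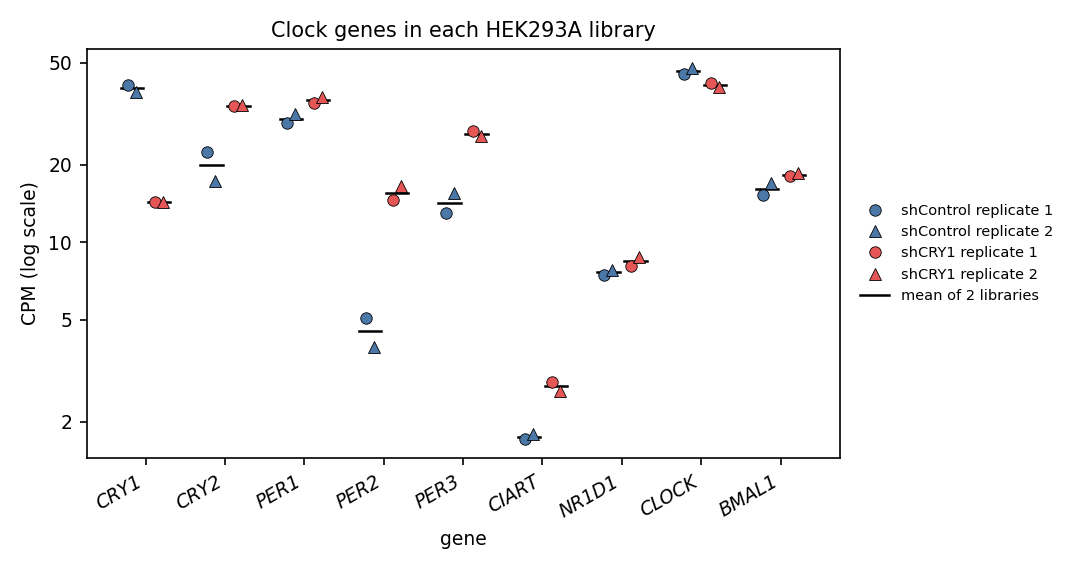
CPM on a log axis for 9 clock genes in each library, with circles for replicate 1, triangles for replicate 2 and a line at the mean of each group of 2 libraries. CRY1 lies lower in both shCRY1 libraries (14.3 CPM on average) than in both shControl libraries (39.8 CPM), and PER2 lies higher (15.6 against 4.50 CPM).

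In the Hippo pathway, the MOB1 adaptor genes fell. MOB1A (Entrez 55233; chromosome 2, 74152528 to 74178879), an activating subunit of the LATS kinases, went from 163 ± 4.09 to 90.6 ± 1.36 CPM (SD, n = 2 each), a log2 change of -0.85 ± 0.11 (limma, adjusted p = 0.00297). MOB1B (Entrez 92597; chromosome 4, 70901851 to 70988168), its paralog, went from 35.0 ± 3.21 to 17.8 ± 0.841 CPM, a log2 change of -0.97 ± 0.14 (limma, adjusted p = 0.0107). The longest annotated 3′ UTR of MOB1A holds 1 copy, and that of MOB1B 2 copies, of the 7-base word described further on. Reads shared by these paralogs may have been divided between them by the counting. Of 38 Hippo pathway components measured, 0 rose, 2 fell and 36 did not pass, with 19 higher and 19 lower, and the same 2 fell when adjusted over the list alone. At an unadjusted p under 0.05 (limma), 1 member was higher and 6 were lower. As a set the components did not pass in camera (adjusted p = 0.390). They passed in the mixed test of fry, which ignores direction (adjusted p = 0.0392). The coactivator genes YAP1 (169 ± 1.93 and 154 ± 3.31 CPM) and WWTR1 (72.3 ± 4.10 and 69.2 ± 4.17 CPM) differed by -0.13 ± 0.10 and -0.06 ± 0.11, and the kinase gene LATS2 by 0.10 ± 0.16.

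Target genes of YAP and TAZ, the coactivators that the Hippo kinases restrain, did not separate the groups beyond the spread of the shControl libraries. Of the 22 genes of the published YAP/TAZ signature, 0 rose and 0 fell by limma over all genes or adjusted over the list alone, and limma-voom also called 0. At an unadjusted p under 0.05, 3 members were higher and 2 lower. Over the signature 16 members were higher and 6 lower, with a median log2 difference of 0.17. CCN1 measured 80.1 ± 36.4 CPM in shControl and 116 ± 12.5 CPM in shCRY1, a log2 difference of 0.61 ± 0.34 (limma, adjusted p = 0.798). CCN2 measured 61.4 ± 32.8 and 73.6 ± 10.7 CPM, ANKRD1 30.7 ± 23.1 and 32.4 ± 8.49 CPM, and AMOTL2 102 ± 32.8 and 119 ± 7.07 CPM. The spread came from shControl, where CCN1 stood at 106 CPM in replicate 1 and 54.3 CPM in replicate 2, and ANKRD1 at 47.0 and 14.4 CPM.

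The YAP/TAZ signature missed the threshold as a set (camera, direction up, adjusted p = 0.0769; 0.929 with an estimated correlation), and the call changed with single libraries. It passed upward without shControl replicate 1 (adjusted p = 2.35e-05) and without shCRY1 replicate 2 (adjusted p = 4.25e-05), while its direction turned down without shControl replicate 2 (adjusted p = 0.667). Without shCRY1 replicate 1 the adjusted p was 0.345. With the replicate number as a block the signature passed upward (camera, adjusted p = 0.00249), as did CCN1 (limma, 8.39e-07) and CCN2 (0.0264). That fit leaves 1 residual degree of freedom per gene, so its limma p-values rest mostly on a variance shared across genes. The signature's median log2 difference was 0.017 within replicate 1 and 0.276 within replicate 2. CCN1 differed by 0.24 and 0.98, and CCN2 by -0.059 and 0.79. Between the replicate numbers the list was lower in replicate 2 (camera, adjusted p = 0.000212, and 0.462 with an estimated correlation). Without shControl replicate 1, CCN1 (adjusted p = 0.0010), CCN2 (0.00569), ANKRD1 (0.0202) and AMOTL2 (0.0349) all passed upward, and CCN1 also passed without shCRY1 replicate 2 (0.0114).

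**Figure D2:**
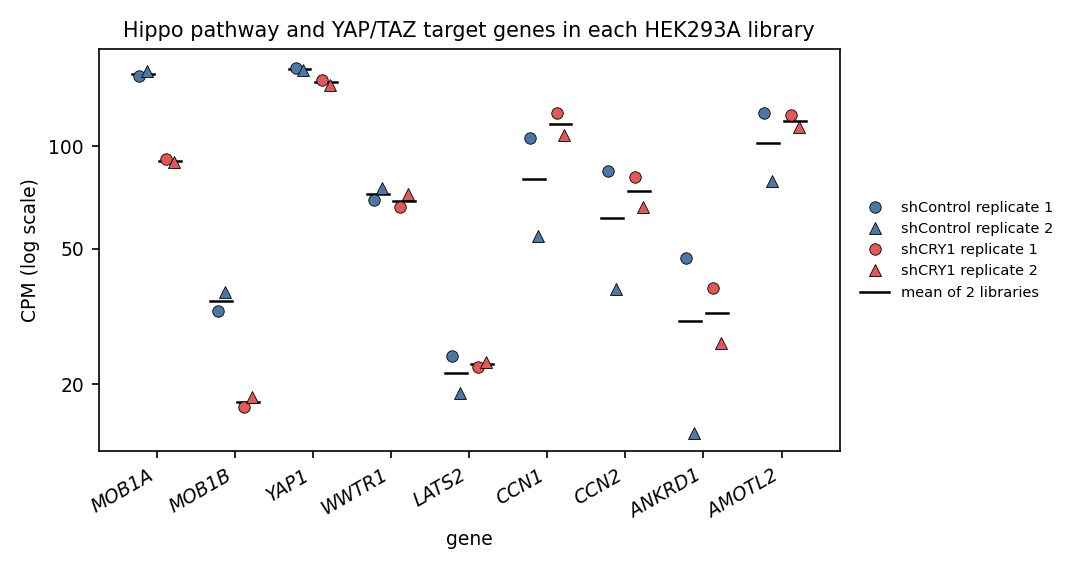
CPM on a log axis for Hippo pathway genes and YAP/TAZ targets in each library, with circles for replicate 1, triangles for replicate 2 and a line at the mean of each group of 2 libraries. MOB1A and MOB1B are lower in both shCRY1 libraries, whereas for CCN2, ANKRD1 and AMOTL2 the shCRY1 values lie between the 2 shControl values.

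Across the 16572 genes tested, 17 rose and 42 fell in shCRY1 (limma, adjusted p under 0.05), of which 6 rose and 13 fell at least 2-fold. At an unadjusted p under 0.05 there were 1259 genes, where 829 would be called by chance. The groups did not overlap for 36.5% of genes, where chance gives 33.3%. The lowest log2 change among genes with a mean of at least 2 CPM was that of KIF1A, a kinesin motor gene of axonal transport, which fell from 41.1 ± 0.0272 to 8.42 ± 0.0883 CPM (SD, n = 2 each), a log2 change of -2.28 ± 0.15 (adjusted p = 2.08e-05). ELK3, an ETS-family transcription factor gene, fell from 28.95 ± 0.641 to 9.85 ± 1.74 CPM, and ITM2C, an integral membrane protein gene, fell from 161 ± 13.0 to 65.4 ± 4.92 CPM. LONRF1 (-1.39), the neuronal splicing factor gene NOVA2 (-1.30), SHISAL1 (-1.20), the ubiquitin ligase receptor gene ZYG11B (-1.16), CCDC85C (-1.08), CTXN1 (-1.07), the mitochondrial ribosomal protein gene MRPL19 (-1.06) and FAM117B (-1.03) were the others of the 12 that fell most, CRY1 included.

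Among genes that rose, SLC2A3, which encodes the glucose transporter GLUT3, had the highest level, going from 165 ± 16.9 to 338 ± 53.9 CPM (SD, n = 2 each), a log2 change of 1.03 ± 0.13 (limma, adjusted p = 0.00297). RAB39A, a small GTPase gene (2.50 ± 0.41), and SPANXN3 (2.55 ± 0.45) rose from 0.613 ± 0.0836 and 0.531 ± 0.0273 CPM. SPANXN3 belongs to a family of similar copies among which reads may be divided. SCIN, which encodes the actin-severing protein scinderin (1.66 ± 0.29), and SYP, which encodes the synaptic vesicle protein synaptophysin (1.55 ± 0.27), rose from 3.68 ± 1.61 and 2.85 ± 0.683 CPM. DHRS2 (0.95), the VEGF receptor gene FLT1 (0.87), NCEH1 (0.84), the retinaldehyde dehydrogenase gene ALDH1A3 (0.83) and NELL2 (0.79) were the others of the 12 that rose most, with PER2 and PER3.

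Several of these genes missed the threshold with a library left out, all in the same direction as before. Without shCRY1 replicate 1 the log2 change was 2.00 for SPANXN3 (adjusted p = 0.452), 2.16 for RAB39A (0.178), 0.78 for FLT1 (0.275), 0.88 for NCEH1 (0.129) and -0.74 for CTXN1 (0.0680). Without shCRY1 replicate 2 it was 0.79 for NCEH1 (adjusted p = 0.147) and 0.76 for ALDH1A3 (0.0594). Without shControl replicate 1 it was 0.81 for FLT1 (adjusted p = 0.0518), 0.83 for NCEH1 (0.0516), 0.63 for ALDH1A3 (0.0694), -1.26 for LONRF1 (0.0530) and -1.14 for CTXN1 (0.0819), and without shControl replicate 2 it was -1.15 for NOVA2 (0.0682) and -1.001 for CTXN1 (0.0988). The totals moved from 17 rising genes to 45 without shControl replicate 1, 58 without shControl replicate 2 and 30 without shCRY1 replicate 2, and from 42 falling genes to 71 without shControl replicate 1 and 85 without shCRY1 replicate 2. The genes called changed as well. Whichever library was left out, some calls of the main fit were lost, and the fewest rising calls were kept without shCRY1 replicate 1. With the replicate number as a block 300 genes rose and 349 fell, in a fit with 1 residual degree of freedom per gene. Limma without robust shrinkage called 7 rising and 25 falling genes, and limma-voom on the recovered reads 11 and 36.

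**Figure D3:**
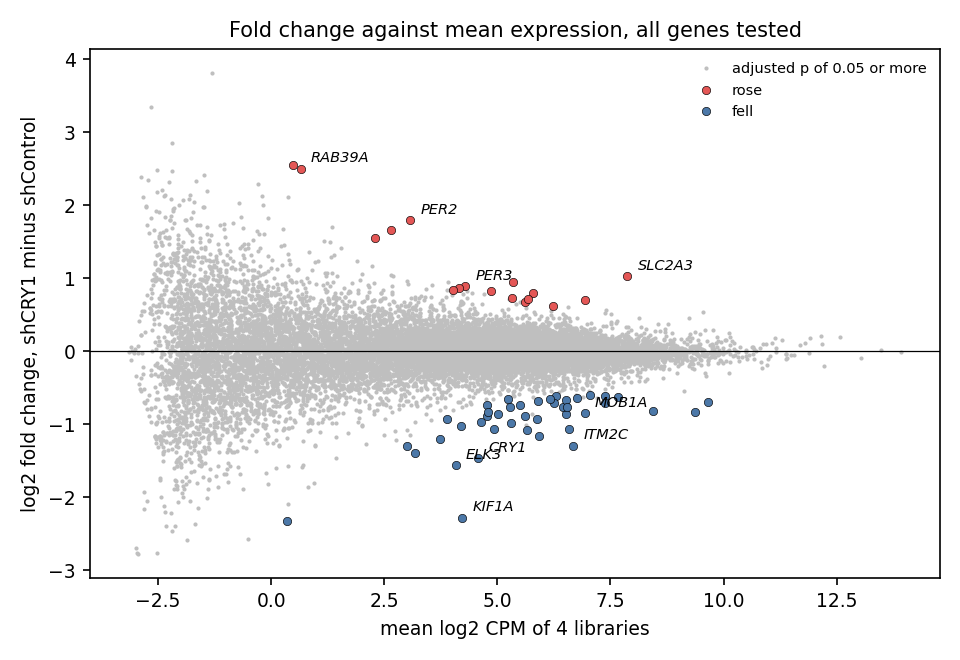
Log2 fold change of shCRY1 over shControl against the mean log2 CPM of the 4 libraries, one point per gene tested, with the 17 genes that rose in red, the 42 that fell in blue and all others in grey. Falls outnumber rises, and the smallest change among called genes is 0.607 log2 units.

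The genes that fell shared a sequence in their 3′ UTRs, a property examined after the calls had been made. Of the 40 falling genes with a searched 3′ UTR, CRY1 left out, 26 (65.0%) held the word ATAGAAC, against 7.19% of all 13997 genes searched. The word was chosen as the most shifted of 15866 on the same genes. With genes permuted within 3′ UTR length classes and the leading word chosen again each time, 5.58 falling genes held that word on average and 20 at most (permutation p = 0.001, one-sided, the smallest that 1000 permutations can give). ELK3, ITM2C, LONRF1, ZYG11B, CCDC85C, MRPL19, FAM117B and MOB1A carried ATAGAAC, whereas KIF1A, NOVA2, SHISAL1, CTXN1 and JUND did not in either 3′ UTR choice. None of the 17 rising genes held it in the 3′ UTR of the isoform with the longest coding sequence (0 of 17), and 1, FLT1, held it in the longest annotated 3′ UTR. Among genes not called, the median log2 difference was -0.06 for 980 genes with the word and 0.01 for 12960 without (permutation p = 0.023, one-sided, with the word chosen again in each of 1000 permutations). It was -0.13 for the 366 genes with ATAGAACA and -0.04 for the 614 with ATAGAAC alone.

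**Figure D4:**
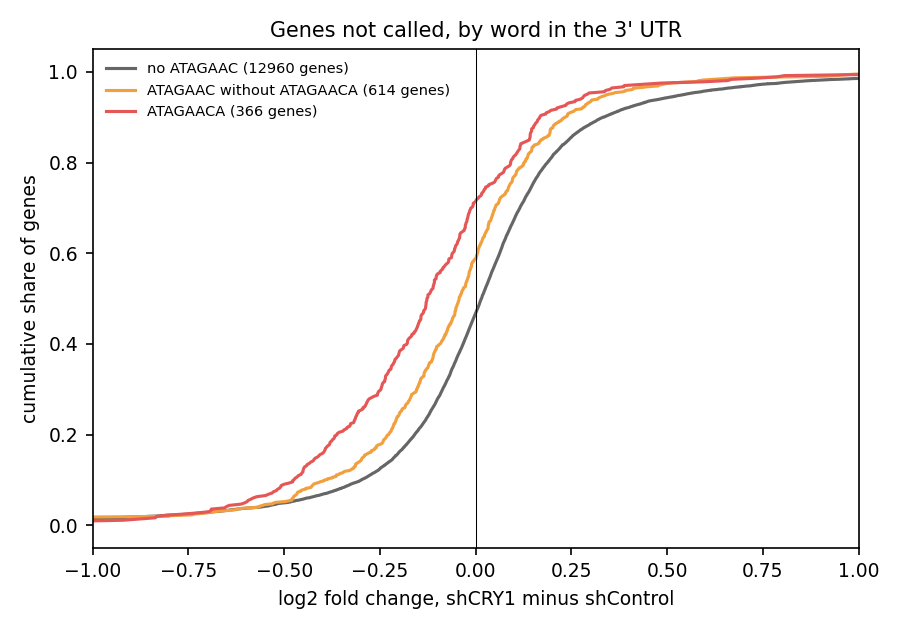
Cumulative share of genes against log2 fold change of shCRY1 over shControl for genes that were not called, split by the 3′ UTR word into 12960 genes without ATAGAAC, 614 with ATAGAAC but not ATAGAACA, and 366 with ATAGAACA. The curves lie further to the left with the longer match, with medians of 0.01, -0.04 and -0.13, and the axis is limited to values between -1 and 1.

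Genes of the unfolded protein and integrated stress response were slightly higher in shCRY1, with 24 of 30 measured members higher and a median log2 difference of 0.21. None passed singly by limma (0 of 30) or limma-voom (0 of 30), while 7 members were higher and 0 lower at an unadjusted p under 0.05. HSPA5, the endoplasmic reticulum chaperone gene, measured 628 ± 157 and 910 ± 214 CPM. The list passed with the preset correlation (camera, adjusted p = 0.000436) and not with an estimated one (adjusted p = 0.929 with an estimated correlation). That estimate was 0.00983, about the preset 0.01, so a higher correlation was not what cost the list its call. The unadjusted p of the list went from 3.11e-05 to 0.0529 (camera), the estimated form using the few residual degrees of freedom of these libraries. The 13 mitochondrially encoded genes, used here as a sign of RNA quality, moved with it, 12 being higher and 1 lower with a median of 0.15 (camera, adjusted p = 0.00335; 0.929 with an estimated correlation). They took 5.87% and 6.12% of reads in the shControl libraries and 6.67% and 6.17% in the shCRY1 libraries, and without shCRY1 replicate 1 their list no longer passed (adjusted p = 0.278). Both lists also passed between the replicate numbers, lower in replicate 2 (camera, adjusted p = 0.00800 for the stress response and 0.0345 for the mitochondrial genes). Neither did so with an estimated correlation (camera, adjusted p = 0.620 for both).

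Epithelial junction genes (20 of 27 higher, median 0.155) and MYC and ribosome biogenesis genes (26 of 30 higher, median 0.09) also passed upward, both with camera adjusted p = 0.0203 and both at 0.929 with an estimated correlation. No member of either list passed over all genes tested by limma or limma-voom, and at an unadjusted p under 0.05 there were 5 junction and 2 MYC list members higher and 0 lower. In the junction list 1 gene, GRHL1 (14.5 ± 0.299 and 23.0 ± 3.59 CPM), rose when adjusted over the list alone. The junction list was lost without shControl replicate 1 (adjusted p = 0.115) or shCRY1 replicate 2 (0.119). The MYC list turned downward past the threshold without shControl replicate 2 (adjusted p = 0.0147) and was lost without shCRY1 replicate 1 (0.901). Its median moved further between replicates 1 and 2, by -0.348 in shControl and -0.188 in shCRY1 (camera between replicate numbers, direction down, adjusted p = 2.54e-18, and 0.462 with an estimated correlation).

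Of the 28 lists tested, 5 passed with the preset correlation and 0 with an estimated correlation or in the directional test of fry, and more passed without shControl replicate 2. The mixed test of fry, which ignores direction, passed for TGF-beta and BMP targets (adjusted p = 0.00111), core clock (0.00164), immediate early (0.0062) and Wnt target genes (0.012). It also passed for E-box and neuronal genes (both 0.0182), Hippo components (0.0392) and S phase genes (0.0475). Between the replicate numbers, with the groups ignored, 13 lists passed with the preset correlation and 0 with an estimated one. Between the groups, the stress response list lost its call at an estimated correlation close to the preset. With so few residual degrees of freedom hardly any list could pass in that form. A miss with an estimated correlation therefore does not by itself decide against a list. The E-box list (adjusted p = 0.113) and the junction list (0.578) did not pass between the replicate numbers. In 23 lists no member passed singly. In the hypoxia and glycolysis list 1 of 30 members rose, SLC2A3, and as a set it did not pass (camera, adjusted p = 0.909). Among 30 immediate early genes 1 fell, JUND, from 97.0 ± 6.22 to 59.9 ± 11.2 CPM (limma, adjusted p = 0.0477), a log2 change of -0.71. It missed the threshold without shCRY1 replicate 1 at -0.51 (adjusted p = 0.404) and without shControl replicate 2 at -0.64 (0.0555). JUN, at 220 ± 14.4 and 157 ± 4.0 CPM, joined it when adjusted over the list alone. Markers of other cell types had no called member and did not pass as sets, with camera adjusted p of 0.566 for 8 blood cell, 0.546 for 10 fibroblast and 0.706 for 9 endothelial genes. The fibroblast list passed upward without shControl replicate 2 (0.0131) and without shCRY1 replicate 1 (0.0184).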

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

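Limma without robust shrinkage and the removal of genes with the 3′ UTR word were added after the data had been seen. CRY1 kept its direction and its call under every setting run, with log2 changes of -1.51 to -1.43 when single libraries were left out. The count of 17 rising genes became 27 without a filter, 11 with limma-voom, 7 without robust shrinkage, 6 without genes holding the word, 3 at an adjusted p under 0.01 and 6 at a fold change of at least 2, and ranged from 16 to 58 with single libraries left out. The count of 42 falling genes became 25 without robust shrinkage, 6 without genes holding the word, and 13 both at an adjusted p under 0.01 and at a fold change of at least 2, and ranged from 32 to 85. The stricter thresholds lower the counts by construction. Of the called genes 1 rising and 29 falling held the word in either 3′ UTR choice, the rule for the removal, and among the 16 and 13 kept the p-values of the main fit, adjusted anew over 15371 genes, call 7 and 6, so most of the further loss comes from the adjustment. For the other settings the cause was not tested. The YAP/TAZ signature passed without a filter (adjusted p = 0.0427) and without genes holding the word (0.0463), and ranged from 2.35e-05 to 0.667 with single libraries left out. The E-box list lost its call with an estimated correlation (0.929) and in fry (0.542), and ranged from 9.03e-09 to 0.00727 with single libraries left out. Of 28 lists 5 passed, against 0 with an estimated correlation, 0 in fry and 5 to 14 with single libraries left out. The MYC and ribosome biogenesis list turned downward without shControl replicate 2 (0.0147), and its adjusted p ranged from 1.325e-13 to 0.901 with single libraries left out. CRY2 passed without a filter (0.0223), at a filter of 1 CPM (0.0407) and at a prior count of 5 (0.0484), whereas PER3, at an unchanged log2 change of 0.90, missed the threshold without robust shrinkage (0.0573) and without genes holding the word (0.0609). Many of the 50 named genes besides CRY1 had no call to lose. Calls were held only by the 12 that rose most, the others of the 12 that fell most, MOB1A, MOB1B and JUND. Among these, 10 lost the call without robust shrinkage, 6 with limma-voom, 6 with upper-quartile factors and 3 at a prior count of 0.1. Other scalings shifted the median of all genes by -0.0016 and -0.010. Where a group kept 1 library, that library was assumed to vary like the other group. DESeq2's Wald test, edgeR's exact test and edgeR's quasi-likelihood test were planned and not run, and limma-voom was the test run on the recovered reads. At this depth and number of libraries, 59.6% of simulated 1.5-fold changes were called, without a simulated difference between replicate numbers. In the data the smallest called change was 1.52-fold, for NACC2, so changes of 1.5-fold or less are poorly resolved.

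With the replicate number as a block, 300 genes rose and 349 fell, the YAP/TAZ signature (adjusted p = 0.00249) and the core clock genes (0.00660) passed as sets, 7 of 28 lists passing in all, and CCN1, CCN2 and CRY2 passed. This fit leaves almost no residual degrees of freedom per gene, so its calls rest mostly on a variance shared across genes. The labels do not say that a number marks a shared batch. Deviations from the group means correlated at 0.258 across genes between libraries with the same number, and the first principal component, 43.7% of the variance, separated the numbers, while the second, 34.8%, separated the groups. Because the labels give no shared batch, the plan held group only and the numbers were not taken to pair the libraries. The main fit thus leaves any difference between the numbers in its spread, which bears on genes that missed the threshold there.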

Other observations

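The tests of the 3′ UTR word and of the clock genes in this part were chosen after the result was seen, except that of MOB1A and MOB1B. Genes of neuronal character, a feature of HEK293 lines, lay on both sides. Of 16 neuronal markers measured, 0 passed over all genes tested by limma or limma-voom, with 11 higher, 5 lower and a median log2 difference of 0.27, while CHGB rose and MAP2 fell when adjusted over the list alone. CHGB, a secretory granule protein gene, measured 0.323 ± 0.0250 and 1.78 ± 0.324 CPM, and MAP2, a dendritic microtubule protein gene, 16.0 ± 2.75 and 8.31 ± 1.31 CPM in shControl and shCRY1. The list did not pass as a set (camera, adjusted p = 0.0975; 0.929 with an estimated correlation), but passed upward without shControl replicate 2 (0.00479). Outside the list, and named after their values were seen, KIF1A, NOVA2 and CTXN1 fell while SYP and STMN3 (0.72 on the log2 scale, adjusted p = 0.0343) rose.

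Some genes had most of their reads in the libraries with replicate number 2 in both groups. Values follow in the order shControl 1, shControl 2, shCRY1 1 and shCRY1 2. The T cell receptor subunit gene CD3E had 0, 52, 0 and 29 reads, the leukocyte gene PTPRC 4, 93, 0 and 38 reads, and the lymphocyte kinase gene LCK 0, 46, 8 and 28 reads. ALDH1A1 had 0, 822, 8 and 140 reads, or 17.5 CPM in shControl replicate 2. None of these 4 genes passed between the groups (limma, adjusted p of 0.982, 0.904, 0.934 and 0.999). CD3E and PTPRC belong to the blood cell list, and LCK and ALDH1A1 were named after their values were seen. Between the replicate numbers the blood cell list was higher in replicate 2 (camera, adjusted p = 0.0233), as was the fibroblast list (0.000313). The endothelial list did not pass (0.575). With an estimated correlation the blood cell and fibroblast lists did not pass either (camera, adjusted p = 0.462 for both).

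The shared 3′ UTR word among the falling genes bears on how their falls can be read. After correction for 3′ UTR length and GC content, ATAGAAC had z = -16.371 where the lowest of 1000 permutations reached -5.66, which argues against length or composition as the source, and the shift of -0.0787 in the median of uncalled genes (permutation p = 0.023, one-sided, with the word chosen again) argues against an effect limited to called genes. A candidate explanation is an off-target seed match of the expressed hairpin, which the empty vector lacks: 26 of 40 falling genes hold the word against 20 at most for the leading word of permuted genes, and the word occurs once in the CRY1 transcript ENST00000008527.9, in coding exon 4 of 13 (chromosome 12, 107001938 to 107001944, GRCh38, minus strand) within GACAAGATCATAGAACTCAATGGTG. The match of ATAGAAC to CRY1 is weak evidence by itself, since 17.7% of the words searched occur in that transcript. Among the next most shifted words, GAACTCA (z = -10.0), TAGAACT (-9.49) and AGAACTC (-7.49) lie in the same stretch of CRY1. TAGAACA (-12.9) and AGAACAT (-8.11) do not occur in that transcript, and overlapping words share genes. Among genes without ATAGAAC, the median log2 difference was -0.046 for the 1100 with GAACTCA and 0.020 for the rest. GAACTCA was picked after the search. The hairpin sequence that would decide whether a seed match is the cause was not given in the sources used here. A lower CRY1 level stays open for all falling genes. Of those searched, 11 lack ATAGAAC in either 3′ UTR choice, among them KIF1A, NOVA2 and JUND, so a match to this word does not cover them. ERBIN, which also fell, had no 3′ UTR searched. A lower CRY1 level cannot be told apart from other effects of this hairpin with a single reagent. Whether these 11 hold the overlapping words GAACTCA (in 10 of the falling genes) or AGAACTC (in 8) was not examined.

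For MOB1A and MOB1B, where the prediction was written before the 3′ UTRs were read for the word, the longest annotated 3′ UTR of both genes (2 of 2) holds it. The word was chosen on the same genes, MOB1A being one of the 26 falling genes with it, so that match is not independent. In the longest 3′ UTR, 72.5% of the falling genes searched hold the word, against 8.49% of all genes searched. MOB1B holds none in the 185-base 3′ UTR of the isoform with the longest coding sequence and 2 in its 6111-base longest one. Their fall may therefore come from a seed match of the expressed shRNA, as a hypothesis, and a change that follows from less CRY1 was not excluded by any value here.

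The rise of PER2 and PER3, and the higher CRY2, differ from this pattern. None of these 3 genes, picked because they were higher, holds the word. Since 7.19% of all genes searched hold it, its absence from 3 genes says little. The label of shCRY1 replicate 2 that names CRY2 is argued against as the true target by CRY2 at 34.14 CPM in that library, above both shControl libraries, with CRY1 below both. A lower CRY1 level stays open for the rise, untested beside indirect effects of the hairpin, since 1 hairpin was used. Another hairpin against CRY1 or a rescue of CRY1 would test it.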
